A study of Mus musculus with 4 samples.

How the data were processed

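Gene expression was measured in mouse liver on 4 whole-transcript microarrays, 1 array for each of 4 groups. Per the labels' protocols, male mice of 10 to 12 weeks carrying floxed Mcu alleles received through the tail vein an adeno-associated virus of serotype 8, in which the hepatocyte-directed TBG promoter drove either Cre recombinase (the knockdown) or no transgene (the control littermates). Surgery removed 70% of the liver 5 weeks later, and the remnant was frozen 30 h after it; the 0 h groups are labelled as the time 0 controls. The series text states pools of 4 animals for each genotype, so each array was treated as 1 pooled sample, grouped by its title. The genotype label of the control arrays reads Wild type. RNA quality was read on a Bioanalyzer and biotin-labelled cDNA was made with the GeneChip WT Plus kit, per the labels' protocols.

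The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of each probe set, so a difference shared by all genes would not be seen. The parameters and versions of that step are not given in the sources used here. The values were rounded to 2 decimals, and the 4 distributions were close but not identical: the medians lay between 3.75 and 3.84, and the SDs over probe sets between 1.83 and 1.96. Among brighter genes the median difference between arrays departed from 0 by up to 0.18, so each list of genes was set against random lists of the same brightness. No detection call or background level was used, and dim values carry more noise and understated folds. No sequencing depth applies, and the number of arrays limits the precision.

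The table held 22206 probe sets. Of these, 19572 carried 1 gene symbol in the platform annotation, none carried several, and 2634 were unnamed and not used. All 19572 matched an Entrez gene ID of the mouse reference annotation of assembly GRCm38.p6, which served for names only. No genome build is given in the sources used here, so no coordinates are printed. A gene with several probe sets, as held for 55 of 19505 genes, took the one with the highest mean over the 4 arrays. An item of the labels is not reported here.

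The 5 comparisons were 30 h minus 0 h in control liver, 30 h minus 0 h in knockdown liver, knockdown minus control at 0 h, knockdown minus control at 30 h, and the difference between the knockdown and the control response. With 1 array per group there is no replicate spread, and no difference has a replicate check. No test was run and no p-value is given, because genes are not replicates. Genes were counted at a difference of at least 2-fold among the 9759 genes whose mean over the 4 arrays was at or above the median of all gene means (3.83), called bright genes here. The 48 gene lists, the comparisons, the size rule and the alternatives were fixed before the data were examined. The lists held 924 genes, of which 831 had a named probe set; the list of genes encoded by mitochondrial DNA had 0 of 15 members with one and was not analysed here. For each of the other 47 lists, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn to match the members over 20 bins of mean expression. A list is said to stand apart when its median lay outside the central 95% of these, which 2.35 of 47 lists would do by chance in each comparison if their genes varied independently. Genes of a list are often co-expressed and then vary together, so this describes these arrays and is not a test.

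The genes named in the text were fixed by rule: in each comparison, the 8 bright genes with the largest positive and the 8 with the largest negative difference, without predicted genes, small and structural RNAs, olfactory, vomeronasal and taste receptors or antigen receptor segments; up to 4 members of each list that stood apart, those with the largest differences in the direction of its median; and the mitochondrial calcium transport genes. The exclusion of symbols starting with Rn was read as Rn followed by a digit, which are structural RNAs, so Rnf125 was kept. A gene named in one comparison may be given its values in the others. Where a gene was chosen after its values were seen, the text says so.

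The list procedure was tested on simulated data built on the comparison at 0 h with 19505 genes. All 50 genes shifted up by 2 on the log2 scale passed the 2-fold size rule, as did all 50 shifted down by 2, 20 of 50 shifted by 1 and 2 of 50 shifted by 0.5, while 97 of 9559 unshifted bright genes passed it. Of the lists of 20 genes, 5% of the unshifted and 100% of those shifted by 0.5 stood apart. The alternatives were no filter on dim genes, genes above percentile 75 of mean expression only, thresholds of 1.5-fold and 3-fold, the mean of a gene's probe sets, median centring, cyclic loess and quantile normalization of the arrays, random lists not matched on expression, the mean in place of the median of a list, bright members only, and members that no other list holds. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with limma 3.58.1 for the normalizations, and matplotlib 3.10.9 for the plots.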

Results

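Liver RNA was profiled on 4 microarrays to ask what loss of Mcu in hepatocytes does to liver regeneration. Mcu encodes the pore-forming subunit of the mitochondrial calcium uniporter, through which calcium enters mitochondria. The groups were control liver at 0 h, control liver 30 h after partial hepatectomy, Mcu knockdown liver at 0 h, and Mcu knockdown liver at 30 h, each 1 array of pooled RNA. Partial hepatectomy removes most of the liver, and the quiescent hepatocytes of the remnant re-enter the cell cycle. Over 22206 probe sets the log2 values ran from 0.94 to 12.9, and pairs of arrays correlated across probe sets with r between 0.953 and 0.974. There were no replicates, so no value below carries an error. A difference between groups is one between 2 arrays, and a difference of responses uses all 4. No group was sampled 30 h after surgery without removal of liver. A response to hepatectomy therefore means 30 h minus 0 h here. Loss of liver cannot be told apart in it from the operation itself or from the time of sampling.

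Mcu was lower on both knockdown arrays. Its single named probe set read 4.77 in control liver at 0 h and 4.30 at 30 h, against 2.83 and 2.63 in the knockdown. This was 3.84-fold lower at 0 h (log2 difference -1.94, the 3rd lowest of 19505 genes) and 3.18-fold lower at 30 h (-1.67, the 23rd lowest). The knockdown values lay at percentiles 29.9 and 22.9 of their arrays, near the dim end, so the folds may be understated. The direction is that of the array titles. The sample descriptions speak of ethanol-fed liver, which no other label mentions, and that of the knockdown 30 h array gives 1 h after surgery where its title and time label give 30 h. The other genes of mitochondrial calcium transport differed less. Micu2, a gatekeeper of the channel, differed by 0.28 at 0 h and -0.31 at 30 h, Micu3 by 0.20 and 0.17, and Smdt1, which encodes the essential regulator EMRE, by 0.32 and 0.04. Mcur1 differed by 0.28 and -0.44, Letm1 by -0.07 and 0.15, Slc25a23 by 0.18 and -0.53, and Slc8b1, the mitochondrial sodium-calcium exchanger, by -0.19 and -0.24. The outer membrane channels Vdac1, Vdac2 and Vdac3 differed by 0.29, -0.13 and 0.09 at 0 h and by -0.35, -0.35 and -0.23 at 30 h.

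**Figure D1:**
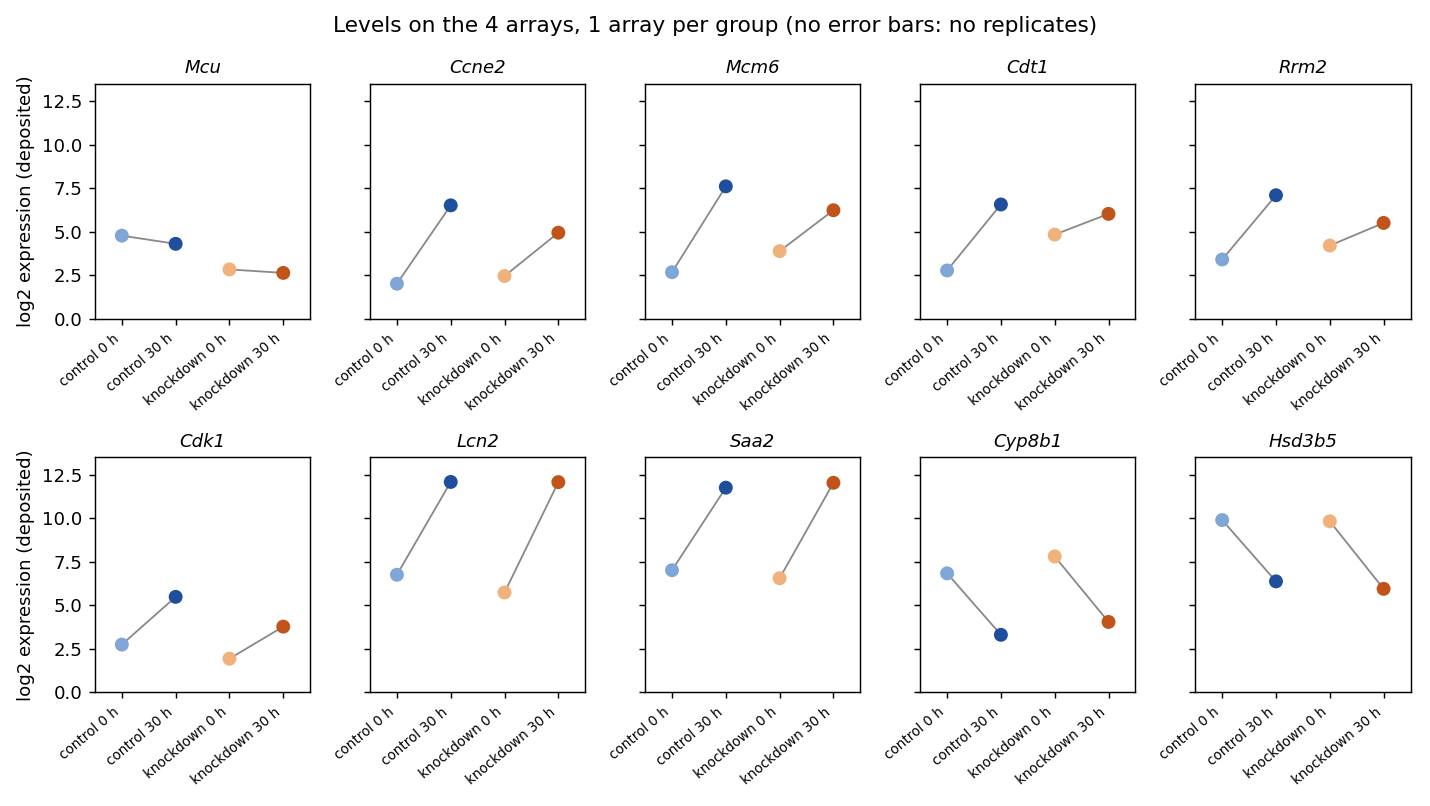
Deposited log2 expression of 10 genes (vertical axis) on the 4 arrays (horizontal axis), 1 point per array, with a line joining 0 h and 30 h within each genotype. Mcu reads 4.77 and 4.30 in control and 2.83 and 2.63 in knockdown liver, Ccne2, Mcm6, Cdt1, Rrm2 and Cdk1 are higher at 30 h by less in the knockdown, and Lcn2, Saa2, Cyp8b1 and Hsd3b5 differ from 0 h to 30 h in the same direction in both genotypes.

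In control liver, genes of DNA replication, cell division and the acute phase were higher 30 h after hepatectomy. The lists of bile acid and cholesterol synthesis, drug metabolism and male-biased genes had medians below 0. The largest positive differences were in Lcn2, an iron-siderophore binding protein of the acute phase (5.33, 40.2-fold), Ly6d (5.30), the replicative helicase subunits Mcm6 (4.93, 30.5-fold) and Mcm4 (4.34), the serum amyloid genes Saa2 (4.74) and Saa1 (4.02), cyclin E2 (Ccne2, 4.50) and the licensing factor Cdt1 (3.79). The largest negative differences were in the carbonic anhydrase Car3 (-4.31, 19.8-fold lower), the bile acid 12-alpha-hydroxylase Cyp8b1 (-3.53), Hsd3b5 (-3.52), the fatty acid elongase Elovl3 (-3.15), the sulfotransferase Sult2a8 (-3.00), Arrdc3 (-2.51), Inmt (-2.47) and the ubiquitin ligase Rnf125 (-2.46). Of 9759 bright genes, 584 were at least 2-fold higher and 157 at least 2-fold lower, so 78.8% of the 741 were higher. That share was 66.2% (417 higher, 213 lower) after quantile normalization and 65.4% over all genes, and among dim genes 234 were higher and 276 lower.

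By list, 29 of 40 DNA replication genes, 25 of 44 mitosis genes and 10 of 18 G1 to S regulators were at least 2-fold higher in control liver at 30 h. Their medians were 1.42, 1.28 and 1.22, each above all 10000 matched random lists. Besides the genes above, they included the ribonucleotide reductase subunit Rrm2 (3.69), E2f8 (2.57), Ccne1 (2.55) and Cdk2 (2.37), and the mitotic genes Pbk (3.68), Cdk1 (2.74), Ube2c (2.58) and Mad2l1 (2.45). The acute phase list had a median of 1.45, with 18 of 26 genes at least 2-fold higher, the metallothionein Mt1 (3.73) among them. Glycolysis genes had a median of 0.49 (random range -0.19 to 0.38), led by the glucose transporter Slc2a1 (1.47), Pfkfb3 (1.44), Aldoa (1.15) and Ldha (1.00). The p53 targets and CDK inhibitors had a median of 0.40 (-0.20 to 0.34), led by Cdkn1a, which encodes p21 (2.62), Cdkn2c (1.71), Mdm2 (1.24) and Eda2r (0.94). Circadian clock genes (0.37, range -0.22 to 0.36) stood apart through Ciart (2.84), Dbp (2.17), Per1 (1.56) and Bhlhe41 (1.11), though 7 of 17 were lower. Neutrophil markers (0.28, range -0.44 to 0.24) were led by Il1b (1.05), Ngp (0.84), S100a8 (0.59) and S100a9 (0.52). Female-biased liver genes (0.28, range -0.27 to 0.27) were led by Cyp17a1 (2.57), A1bg (0.99), Cyp4a14 (0.89) and Nipal1 (0.86).

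All 18 male-biased liver genes were lower in control liver at 30 h, with a median of -0.60 (random range -0.07 to 0.44). Hsd3b5 and Elovl3 led them, followed by the organic anion transporter Slco1a1 (-1.62) and Selenbp2 (-1.53). Cholesterol synthesis had a median of -0.30 (-0.03 to 0.45), with 14 of 19 genes lower, among them Sc5d (-0.96), Hmgcs1 (-0.77), Pmvk (-0.77) and Fdps (-0.62). Bile acid synthesis and transport had a median of -0.24 (-0.07 to 0.41), and besides Cyp8b1 and Slco1a1 included Slc51a (-1.14) and Cyp27a1 (-0.86). Drug metabolism had a median of -0.17 (-0.01 to 0.43), with Ugt2b1 (-1.58), Ces1d (-1.05), Cyp2c54 (-1.02) and Gsta3 (-0.88) the lowest. Of its 25 genes, 15 were lower and 10 higher, with 3 at least 2-fold lower and 4 at least 2-fold higher. The 6 measured erythroid markers had a median of -0.58 (-0.44 to 0.46), led by Epb42 (-1.34), Alas2 (-1.10), Klf1 (-0.60) and Slc4a1 (-0.55). The place of the circadian list outside its range held in 4 of 8 alternative settings and that of the female-biased list in 5 of 8. The bright female-biased members had a median of -0.41 at percentile 0.375, so they stood apart as lower, the opposite direction. Bile acid, drug metabolism and p53 target genes held theirs in 6 of 8, with medians of -0.08 (bile acid, members that no other list holds) and 0.20 (p53 targets, bright members) and a mean of -0.0048 (drug metabolism) inside the ranges; the erythroid mean (-0.31) and, against unmatched random lists, the neutrophil median were inside too, and neither list had enough bright members to be scored.

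In knockdown liver, the acute phase genes were again the highest at 30 h and 6 of the 8 genes with the largest negative differences were those of control liver, while the cell cycle genes were higher by less. The largest positive differences were in Lcn2 (6.34, 81.0-fold), the metallothioneins Mt2 (6.01) and Mt1 (4.83), Saa2 (5.48), Ly6d (4.80), the orosomucoid Orm2 (4.33), the lysophospholipid transporter Mfsd2a (4.18) and Saa1 (4.02). The largest negative differences were in Car3 (-4.38, 20.8-fold lower), Hsd3b5 (-3.88), Cyp8b1 (-3.76), Elovl3 (-3.05), Cited2 (-2.90), Rnf125 (-2.84), the glycogen-targeting phosphatase subunit Ppp1r3c (-2.80) and Sult2a8 (-2.72). Of the bright genes, 258 were at least 2-fold higher and 267 at least 2-fold lower; among dim genes 273 were higher and 125 lower.

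The acute phase list had a median of 1.49 in the knockdown, with 14 of 26 genes at least 2-fold higher. DNA replication genes had a median of 0.75, with 18 of 40 at least 2-fold higher, led by Rrm1 (2.72), Mcm4 (2.37), Mcm6 (2.35) and the sliding clamp Pcna (2.0). Mitosis genes had a median of 0.49, with 10 of 44 at least 2-fold higher, led by Ube2c (1.93), Cdk1 (1.84), Nek2 (1.81) and the proliferation marker Mki67 (1.55). G1 to S regulators had a median of 0.52, with 2 of 18 at least 2-fold higher, Ccne2 (2.49) and Ccne1 (1.77); next came Skp2 (0.82) and Ccnd3 (0.72). Immediate early genes, the transcription factors and regulators induced first by growth signals, had a median of 0.50 (random range -0.28 to 0.20), led by Myc (1.66), Ier3 (1.53), Egr1 (1.43) and Atf3 (1.37). Female-biased genes (0.33, range -0.24 to 0.25) were led by Cyp17a1 (3.17) and Cyp4a14 (1.07), followed by Cyp3a41a (0.79) and Cyp2b13 (0.76). Extracellular matrix genes (0.29, range -0.26 to 0.23) were led by Col1a2 (1.21), Lamc1 (1.03), Fn1 (1.00) and Timp1 (0.94). Clock genes (0.29, range -0.28 to 0.24) were led by Ciart (1.72), Dbp (1.45), Per1 (0.97) and Nr1d2 (0.68). ER chaperones (0.27, range -0.30 to 0.22) were led by Creld2 (1.25), Hyou1 (0.70), Dnajb9 (0.47) and Xbp1 (0.47). Glycolysis (0.27, range -0.27 to 0.25) was led by Pfkfb3 (2.05), the lactate transporter Slc16a3 (1.47), Hk2 (0.94) and Ldha (0.90). Growth factors and receptors of regeneration had a median of 0.19 at percentile 97.6, with Igfbp1 (1.53), Tnfrsf1a (0.76), Tgfb1 (0.58) and Notch1 (0.58) the highest.

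Male-biased genes had a median of -0.62 in the knockdown (random range -0.28 to 0.22), with Serpina12 (-1.75) and Selenbp2 (-1.67) after Hsd3b5 and Elovl3. Bile acid synthesis and transport had a median of -0.61 (-0.27 to 0.19), with 16 of 21 genes lower, among them Slco1a1 (-1.64), Nr0b2 (-0.92) and Baat (-0.86). Fatty acid synthesis had a median of -0.39 (-0.28 to 0.19), led by the carbohydrate-responsive factor Mlxipl (-1.81), the desaturase Scd1 (-1.46), Acss2 (-1.31) and Acacb (-0.75). Drug metabolism had a median of -0.32 (-0.25 to 0.18), led by Ugt2b1 (-1.98), Cyp2f2 (-1.38), Gsta3 (-1.30) and Ces2a (-0.97). Interferon response genes also had a median of -0.32 (-0.22 to 0.26), led by Rtp4 (-1.45), Rsad2 (-1.03), Irf7 (-0.95) and Ifit2 (-0.69). Subunits of complex I and the other respiratory chain complexes had a median of -0.22 (-0.18 to 0.11), with 36 of 49 lower but none at least 2-fold; Sdha (-0.94), Ndufb5 (-0.59), Ndufb8 (-0.55) and Uqcrc1 (-0.54) were the lowest. Markers of 3 resident non-hepatocyte cell types were lower too, while those of cholangiocytes had a median of 0.27, inside their range. Sinusoidal endothelial markers had a median of -0.59 (-0.31 to 0.24), with Clec4g (-1.55), Dnase1l3 (-1.19), Stab2 (-0.92) and Stab1 (-0.88) the lowest. Kupffer cell markers had a median of -0.39 (-0.35 to 0.24), with Adgre1 (-0.65), C1qa (-0.62), Clec4f (-0.59) and C1qc (-0.45) the lowest, and their mean was -0.04, inside its range. Stellate cell markers had a median of -0.35 (-0.31 to 0.26), with Colec11 (-1.0), Lox (-0.63), Vipr1 (-0.63) and Hand2 (-0.46) the lowest. The growth factor list kept its place outside the range in 4 of 8 alternatives, and the glycolysis list in 6 of 8. The means of the respiratory chain (-0.17), drug metabolism (-0.25), ER chaperone (0.29) and clock (0.04) lists and the bright members of the interferon (-0.38), extracellular matrix (0.23) and stellate (-0.35) lists also lay inside their ranges.

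**Figure D2:**
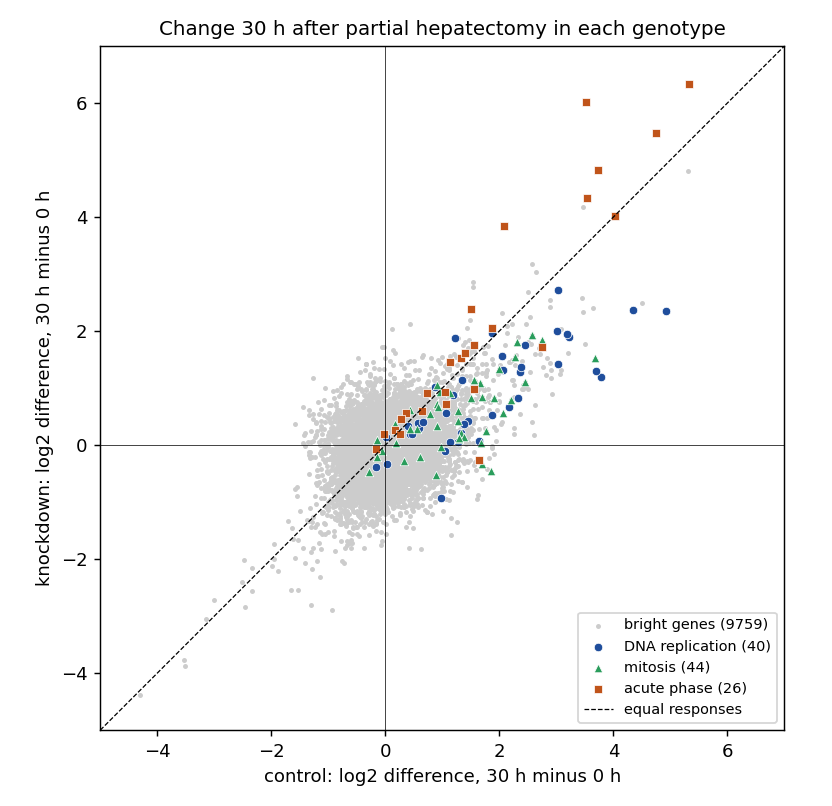
Log2 difference from 0 h to 30 h in control liver (horizontal axis) and in knockdown liver (vertical axis), 1 point per gene: 9759 bright genes in grey, all measured genes of 3 lists in colour, and a dashed line where the responses are equal. The DNA replication and mitosis genes lie mostly below the line, with medians of 1.42 and 1.28 in control against 0.75 and 0.49 in knockdown liver, and 18 of the 26 acute phase genes lie above it and 7 below (medians 1.45 and 1.49).

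At 0 h, knockdown liver had higher levels of interferon response genes and of Kupffer, sinusoidal endothelial and stellate cell markers, and lower levels of ER chaperones. The sinusoidal endothelial and stellate lists came inside their ranges after cyclic loess, and cholangiocyte markers had a median of 0.07, inside their range. The largest positive differences from control were in Slc19a1, the reduced folate carrier (2.27, 4.82-fold), Socs3, a feedback inhibitor of cytokine signalling (2.07), Cdt1 (2.06), Gas7 (2.03), Akr1c19 (1.86), Cdkn1a (1.84), Ccdc97 (1.83) and the lysosomal sulfatase Arsa (1.81). The largest negative differences were in Mt2 (-2.13, 4.38-fold lower), Cyp26a1, which degrades retinoic acid (-1.98), Serpina7, thyroxine-binding globulin (-1.53), the primase subunit Prim1 (-1.49), Fam71b (-1.48), Rarb, a retinoic acid receptor (-1.48), Slc51b (-1.47) and Cep164 (-1.43). Of the bright genes, 122 were at least 2-fold higher and 62 at least 2-fold lower, but among dim genes 160 were higher and 182 lower, so 53.6% of the 526 over all genes were higher. This comparison had the narrowest spread of the 5, with a robust SD across bright genes of 0.34.

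The interferon response list had a median of 0.52 at 0 h, above all 10000 random lists (range -0.22 to 0.23), with 15 of 19 genes higher, among them Isg15 (1.24), Irf7 (1.10), Ifit1 (0.94) and Gbp2 (0.89). Kupffer cell markers had a median of 0.39 (-0.18 to 0.29), with Vsig4 (0.85) and the complement genes C1qc (0.72) and C1qb (0.59) ahead of Cd5l (0.51). Sinusoidal endothelial markers had a median of 0.29 (-0.19 to 0.28), with Gpr182 (1.09), Tek (0.97), Fcgr2b (0.81) and Stab1 (0.65) the highest. Stellate cell markers also had a median of 0.29, at percentile 97.6, with Rgs5 (1.20), Vipr1 (0.80), Acta2 (0.77) and Hand2 (0.63) the highest. The p53 targets and CDK inhibitors had a median of 0.32 (-0.15 to 0.24), with Cdkn1a followed by Eda2r (0.73), Trp53inp1 (0.70) and Cdkn2c (0.67). Fatty acid synthesis had a median of 0.30 (-0.07 to 0.25), with 16 of 18 genes higher, among them Elovl5 (0.73), Scd1 (0.69), Acss2 (0.65) and Thrsp (0.56). Antioxidant response genes had a median of 0.25 at percentile 97.8, with 18 of 19 higher and Gstm2 (0.95), Gstm3 (0.56), Prdx3 (0.52) and Pgd (0.33) the highest. ER chaperones had a median of -0.21 (-0.03 to 0.26), with 12 of 16 lower, led by Creld2 (-1.17), Dnajb9 (-0.81), Hspa5, which encodes BiP (-0.55), and Edem1 (-0.51). Mitosis genes had a median of -0.28 (-0.15 to 0.15), led by Kif22 (-1.0), Kif2c (-0.91), Nek2 (-0.89) and Cdk1 (-0.81), but the bright members had a median of -0.11, inside their range, while DNA replication genes had a median of 0.06, inside their range. The acute phase list (-0.02) and the drug metabolism list (-0.01) lay below random lists whose own medians were mostly above 0. In the acute phase list Lcn2 (-1.02), Orm2 (-0.69) and Mt1 (-0.69) followed Mt2, and in the drug metabolism list Cyp2c38 (-0.46), Cyp3a13 (-0.45), Cyp2c55 (-0.38) and Ces1d (-0.33) were the lowest. The sinusoidal endothelial and stellate lists came inside their ranges after cyclic loess (0.22 and 0.24), as did the drug metabolism list, whose mean was 0.06. Against random lists not matched on expression the ER chaperone, acute phase and drug metabolism lists lay inside their ranges (percentiles 3.07, 35.5 and 40.1).

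At 30 h after hepatectomy, nearly all measured cell cycle genes were lower in knockdown than in control liver. Of the 102 genes of the 3 cell cycle lists, 96 were lower and 35 at least 2-fold lower, with a median of -0.80 (1.74-fold lower). Mitosis genes had a median of -0.91 (random range -0.10 to 0.23), with 42 of 44 lower, led by Pbk (-2.58), the checkpoint kinase Bub1 (-1.82), Cdk1 (-1.71) and the kinetochore gene Nuf2 (-1.44). DNA replication genes had a median of -0.80 (-0.20 to 0.15), with 39 of 40 lower, led by Gins1 (-1.79), Mcm4 (-1.60), Rrm2 (-1.59) and Mcm3 (-1.52). G1 to S regulators had a median of -0.36 (-0.28 to 0.23), with 15 of 18 lower, led by Ccne2 (-1.57), Rbl1 (-1.54), E2f8 (-1.53) and Cdk2 (-1.34). Ribosome biogenesis, which supplies growing cells with ribosomes, had a median of -0.41 (-0.31 to 0.09), with Nop14 (-0.97), Utp20 (-0.92), Nop58 (-0.83) and Npm1 (-0.64) the lowest, though its mean of -0.23 lay inside its range. Cholesterol synthesis genes were higher, with a median of 0.38 (-0.30 to -0.01) and 15 of 19 above control, led by Hmgcs1 (1.09), Sqle (0.96), Mvd (0.78) and Cyp51 (0.63).

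Immediate early genes had a median of 0.22 at 30 h (random range -0.34 to 0.11), led by Fosb (1.31), Myc (0.98), Egr2 (0.90) and Fosl1 (0.67), with 7 of 18 lower. The acute phase list (0.11, range -0.23 to 0.00) was led by Saa3 (1.77), Serpina3n (0.90), Il1rn (0.42) and Mt1 (0.41). Lipid droplet and lipid uptake genes (0.17, range -0.33 to 0.12) were led by Cidec (0.53), Lipe (0.47), Plin4 (0.27) and Mogat1 (0.24). Growth factors and receptors (0.12, range -0.28 to 0.10) were led by Ereg (0.80), Wnt2 (0.73), Igfbp1 (0.72) and Angpt2 (0.53). Male-biased genes (0.06, range -0.27 to 0.02) were led by Cspg5 (0.76), Cyp7b1 (0.52), Serpina12 (0.31) and Ugt2b38 (0.25). Among single bright genes the largest positive differences were in Krtap9-1 (1.91, 3.76-fold), Saa3, Smim22 (1.73), Pheta2 (1.71), Krtap5-4 (1.63), Lmx1a (1.55), the integrin Itgb3 (1.38) and Tnfaip3, an inhibitor of NF-kappaB signalling (1.37). The largest negative differences were in the histone gene H2bc18 (-2.07, 4.20-fold lower), Ptcd3, a mitochondrial translation factor (-1.89), the microtubule-binding Clasp1 (-1.83), Slc51b (-1.82), the recycling endosome GTPase Rab11a (-1.79), Gemin6 (-1.77), the kinase Clk4 (-1.76) and the histamine methyltransferase Hnmt (-1.65). In all, 111 bright genes were at least 2-fold higher and 211 at least 2-fold lower, so 34.5% of the 322 were higher; this share was 17.2% (71 higher, 341 lower) after median centring, 41.5% after cyclic loess and 43.2% after quantile normalization. The direction turned with the dim genes, of which 292 were higher and 152 lower, so 52.6% of the 766 over all genes were higher. After cyclic loess the G1 to S list (-0.24, percentile 4.73) and the growth factor, lipid droplet and male-biased lists came inside their ranges, the male-biased median was -0.04 after median centring and -0.02 over members that no other list holds, and the bright growth factor members had a median of -0.01. Against random lists not matched on expression, 5 of the 10 lists kept their place, cholesterol synthesis being the only higher one among them.

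**Figure D3:**
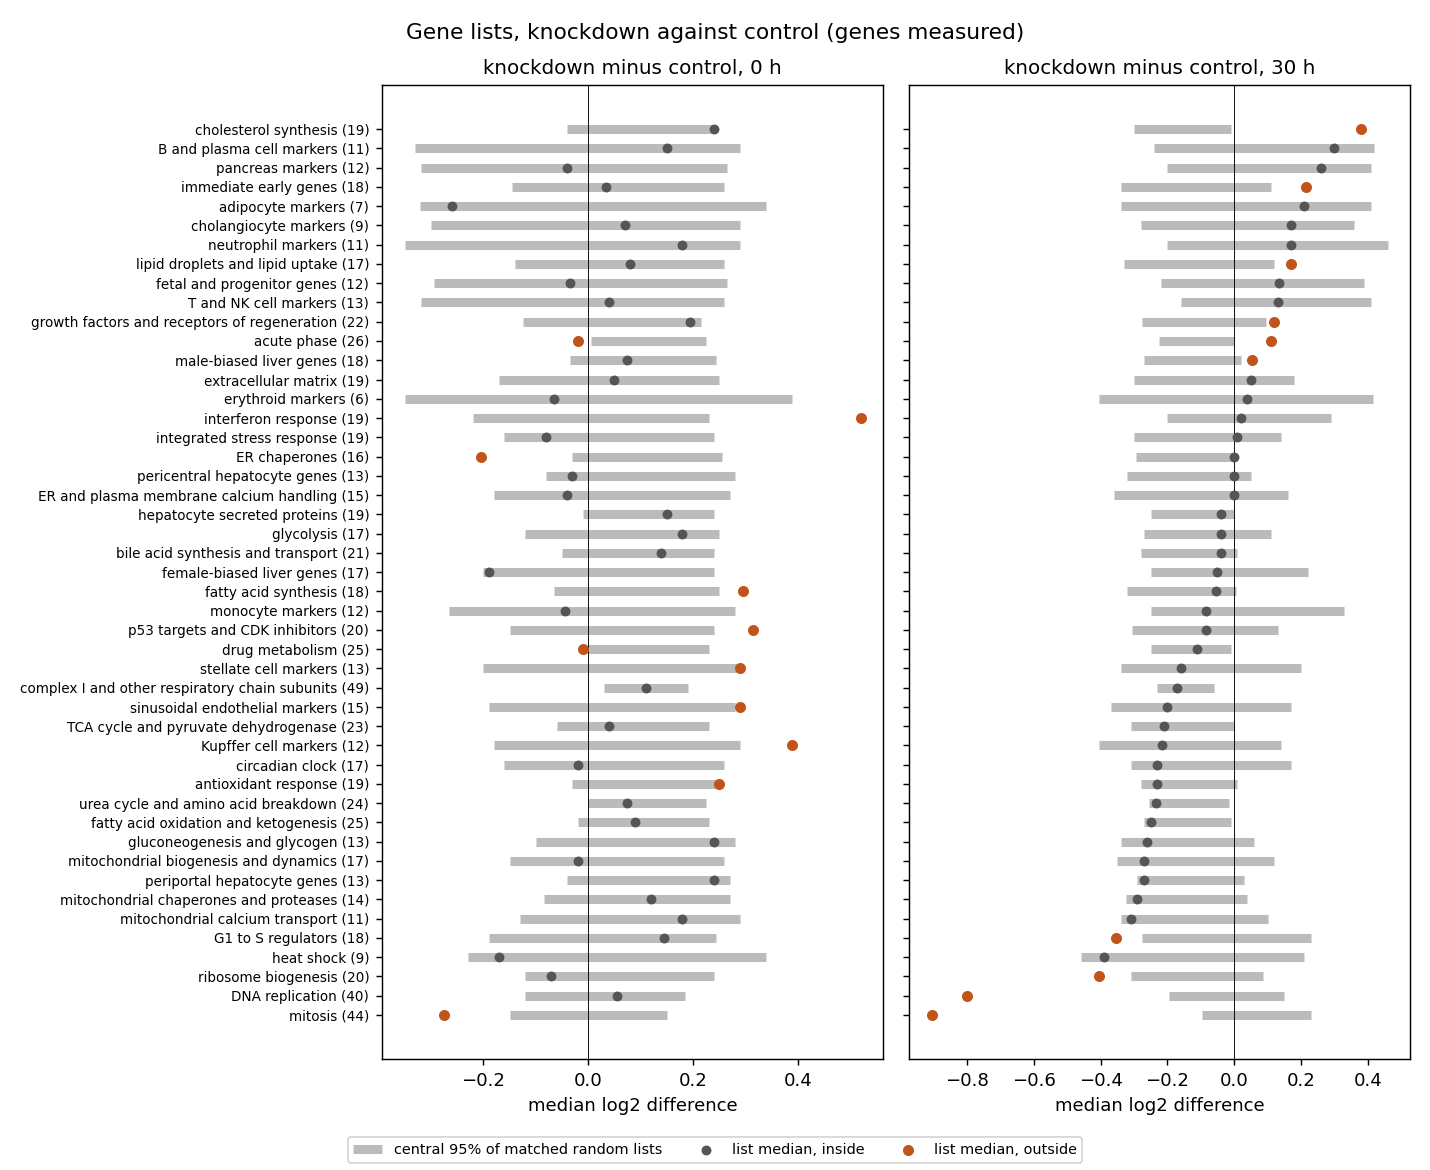
Median log2 difference between knockdown and control liver (horizontal axes) of 47 gene lists (vertical axis, measured genes in brackets) at 0 h and at 30 h, with bars for the central 95% of 10000 random lists matched on expression and orange points for lists outside it. At 30 h the mitosis (-0.91) and DNA replication (-0.80) lists lie far to the left of their bars and cholesterol synthesis (0.38) to the right of its bar, and at 0 h the interferon response list (0.52) lies farthest to the right.

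The responses to hepatectomy ran in the same direction in both genotypes for most genes at least 2-fold different in control liver, and the cell cycle lists were among those that differed most. Of the 584 bright genes at least 2-fold higher at 30 h in control liver, 472 (80.8%) were also higher in knockdown liver, with medians of 1.31 and 0.50, and 153 were at least 2-fold higher in both, where independent lists of these sizes would share 15.4. Of the 157 lower genes, 113 (72.0%) were lower in both, with medians of -1.17 and -0.65, and 57 were at least 2-fold lower in both against 4.30 for independent lists. The genes were chosen by their size in control liver, so part of the smaller median in the knockdown is what selection alone would give. The cell cycle lists were not chosen that way, and 64 of their 102 genes were at least 2-fold higher in control liver, 30 in knockdown liver and 28 in both, with medians of 1.33 (2.51-fold) and 0.55 (1.46-fold). The response was smaller in the knockdown for 89 of the 102. The 2 responses share no array, and across bright genes they correlated with r = 0.456, where genes are not independent replicates. The differences between knockdown and control liver did not recur in this way from 0 h to 30 h (r = -0.018 across bright genes). Among bright genes, Cdpf1, Gm20852 and Pheta2 were at least 2-fold higher at both times, 3 genes against 1.39 for independent lists. Hook3 and Slc51b were at least 2-fold lower at both times, 2 against 1.34. Apart from Pheta2 and Slc51b these genes were chosen after their values were seen. Mcu was also at least 2-fold lower at both times (-1.94 and -1.67), but its mean of 3.63 left it out of the bright genes. Of the 122 genes higher at 0 h, 41.8% were higher at 30 h, and of the 62 lower, 46.8% were lower.

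As a difference of responses, knockdown minus control, DNA replication had a median of -1.01 (random range -0.28 to 0.17), mitosis -0.67 (-0.16 to 0.30) and G1 to S regulators -0.70 (-0.39 to 0.29). The largest negative values among their genes were Cdt1 (-2.60), Mcm6 (-2.58), Rrm2 (-2.39) and Mcm4 (-1.97) in replication, Prc1 (-2.32), Pbk (-2.15), Bub1 (-2.02) and Nusap1 (-1.64) in mitosis, and E2f8 (-2.16), Ccne2 (-2.01), Cdk2 (-1.83) and Cdc25a (-1.82) in the G1 to S list. Part of the Cdt1 and Mcm6 values came from 0 h, where they read 4.83 and 3.88 in knockdown against 2.77 and 2.67 in control liver. At 30 h they read 6.02 and 6.23 in knockdown against 6.56 and 7.60 in control liver. Lists that differed at 0 h enter this comparison with the opposite sign, since the 0 h arrays are part of it. This holds for sinusoidal endothelial markers (-0.85, range -0.50 to 0.24; Bmp2 -1.64, Fcgr2b -1.21, Tek -1.14 and Gpr182 -1.09), Kupffer cell markers (-0.67, range -0.56 to 0.19; Vsig4 -1.48, Adgre1 -1.07, Marco -1.03 and C1qc -0.99) and the interferon response (-0.54, range -0.30 to 0.38; Rsad2 -0.94, Irf7 -0.92, Gbp2 -0.79 and Isg15 -0.73), all inside their ranges at 30 h; the bright interferon members (-0.54, percentile 4.18) were inside theirs. It also holds for the antioxidant response (-0.52, range -0.45 to -0.05), led by Gstm2 (-1.93), Gstm3 (-1.44), Nqo1 (-1.27) and Prdx3 (-0.75), and for ER chaperones (0.16, range -0.47 to -0.06), led by Creld2 (1.51), Dnajb9 (1.01), Hyou1 (0.63) and Sdf2l1 (0.56). Periportal hepatocyte genes had a median of -0.53 (-0.48 to -0.02), with Aldh1b1 (-1.40), G6pc (-1.19), Hal (-0.74) and Uroc1 (-0.66) the lowest. The acute phase list (0.19, range -0.38 to -0.08) was led by Mt2 (2.49), Saa3 (1.76), Mt1 (1.10) and Lcn2 (1.01). This list also lay below its range at 0 h (-0.02, percentile 0.74), where Mt2, Mt1 and Lcn2 differed by -2.13, -0.69 and -1.02. Saa3 read 7.17 in control and 7.18 in knockdown liver at 0 h and differed by 1.77 at 30 h, where the list stood apart as higher (0.11). Cholesterol synthesis (0.14, range -0.47 to -0.06) was led by Hmgcs1 (0.78), Sqle (0.66), Cyp51 (0.58) and Idi1 (0.50). Immediate early genes (0.17, range -0.48 to 0.14) were led by Ier3 (1.54), Myc (1.53), Egr3 (1.24) and Fosb (1.18). The male-biased list (-0.04) lay at percentile 97.6 and held this place in 3 of 8 alternatives, with a median of 0.13 after cyclic loess, although Serpina12 (-1.08), Susd4 (-0.61), Cyp2d9 (-0.56) and Hsd3b5 (-0.36) responded lower.

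Among single bright genes the difference of responses was largest and negative in Csk (-2.73, 6.63-fold), Cdt1, Rab11a (-2.59), Mcm6, Hsd17b6 (-2.54), the chromatin protein Mtf2 (-2.49), the phospholipid transfer protein Pltp (-2.46) and Slc19a1 (-2.44). It was largest and positive in Mt2, the kisspeptin receptor Kiss1r (2.44), Wdfy1 (2.12), Abcc10 (2.07), the potassium channel Kcnk6 (2.0), Pramel39 (1.95), Fam189a2 (1.95) and Zfp979 (1.93). Slc19a1 and Mt2 differed between genotypes mainly at 0 h. Slc19a1 read 2.77 in control and 5.04 in knockdown liver at 0 h, and 5.38 and 5.21 at 30 h. Mt2 read 8.15 and 6.02 at 0 h, and 11.67 and 12.03 at 30 h. At least 2-fold differences of responses were negative in 725 bright genes and positive in 316, so 30.4% of the 1041 were positive; this share was 41.4% (376 positive, 532 negative) after cyclic loess and 42.1% (375 and 515) after quantile normalization. Dim genes ran the other way, with 855 positive and 411 negative, so 50.8% of the 2307 over all genes were positive. A difference of responses combines the variation of 4 arrays (robust SD across bright genes 0.55), and against random lists not matched on expression none of the 5 higher lists kept its place, while all 8 lower lists did.

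With the values as deposited, the mitochondrial lists and several other lists did not stand apart between knockdown and control liver at either time. Respiratory chain subunits had medians of 0.11 at 0 h and -0.17 at 30 h, TCA cycle and pyruvate dehydrogenase 0.04 and -0.21, and fatty acid oxidation and ketogenesis 0.09 and -0.25. Mitochondrial chaperones and proteases had medians of 0.12 and -0.29, mitochondrial biogenesis and dynamics -0.02 and -0.27, mitochondrial calcium transport with Mcu included 0.18 and -0.31, and ER and plasma membrane calcium handling -0.04 and 0.00. Urea cycle and amino acid breakdown had 0.08 and -0.24, gluconeogenesis and glycogen 0.24 and -0.26, hepatocyte secreted proteins 0.15 and -0.04, and pericentral hepatocyte genes -0.03 and 0.00. The integrated stress response had medians of -0.08 and 0.01, and heat shock genes -0.17 and -0.39. Bright genes in general lay below 0 at 30 h (median -0.11), which the matched random lists share. The medians of mitochondrial calcium transport, fatty acid oxidation, mitochondrial chaperones, urea cycle and heat shock genes were lower than that. They lay near the lower edge of their ranges, at percentiles 4.75 to 5.82. Markers of other cell types differed by 0.07 and 0.17 (cholangiocytes), -0.05 and -0.09 (monocytes), 0.04 and 0.13 (T and NK cells), 0.15 and 0.30 (B and plasma cells), -0.26 and 0.21 (adipocytes) and -0.04 and 0.26 (pancreas), and fetal and progenitor genes by -0.04 and 0.14. Apart from the respiratory chain subunits, which were lower at 30 h within the knockdown, these 19 of the 47 lists stayed inside their ranges in all 5 comparisons as deposited. Other settings gained calls at 30 h. Cyclic loess and quantile normalization each put 9 lists outside their ranges, 6 of them among the 10 as deposited, and list means put 12 outside, 7 of them among the 10. The gained lists are not named here and may include some of these 19.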

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

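The tests weighed here were all chosen after the result was seen. Of the genes named by rule, 18 responded to hepatectomy in opposite directions in the 2 genotypes, by at least 1.5-fold each way. With 1 array per group this difference was not tested. The rule named genes by their largest differences of responses and between genotypes, which favours opposite responses. The number 18 is therefore no measure of how common they are. Higher at 30 h in control and lower in knockdown liver were Csk (1.15 in control, -1.58 in knockdown), Mtf2 (1.62, -0.87), Hsd17b6 (1.60, -0.94), Rab11a (1.25, -1.34), Pltp (0.63, -1.83), Clk4 (1.02, -1.15), Gas7 (1.19, -0.82), Bhlhe41 (1.11, -0.62) and Clasp1 (0.84, -0.87). Lower in control and higher in knockdown liver were Slc16a3 (-1.29, 1.47), Kiss1r (-1.26, 1.18), Wdfy1 (-1.45, 0.67), Abcc10 (-1.06, 1.01), Pramel39 (-1.34, 0.61), Krtap9-1 (-0.68, 1.21), Slc51a (-1.14, 0.59), Fam71b (-0.78, 0.92) and Cep164 (-0.60, 1.11). They include a tyrosine kinase, a recycling endosome GTPase, a lactate transporter and a bile acid transporter subunit.

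Opposite responses of this size were counted over all genes. Among 9759 bright genes there were 118 (79 higher in control, 39 lower), or 1.21%, and among dim genes there were 189 (1.94%). If the 2 responses were unrelated, 277 bright genes would be expected, but they correlate across bright genes (r = 0.456), which lowers the number whatever the source of the opposite genes. The count therefore decides nothing, and unrelated variation cannot be told apart from a changed response without Mcu, which was not tested.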

How the results depend on the processing

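The alternatives here were all planned. No paired analysis was possible because each group is 1 pool and the labels do not say whether the same animals gave the 0 h and 30 h tissue. Leaving out an array would remove a group. The number of genes past the size rule followed the filter and the threshold, by their construction. In the order control response, knockdown response, knockdown against control at 0 h, the same at 30 h, and difference of responses, the counts were 741, 525, 184, 322 and 1041. Without the filter on dim genes they were 1251, 923, 526, 766 and 2307, above percentile 75 of mean expression 356, 275, 38, 77 and 329, at 1.5-fold 2494, 2064, 1189, 1839 and 3140, and at 3-fold 172, 119, 14, 24 and 156. Under the mean of probe sets, median centring, cyclic loess and quantile normalization they stayed within 1.5 times.

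Of the 68 list medians outside their ranges, 23 moved by more than 1 SD of the random medians under quantile normalization, 21 as means, 19 under cyclic loess, 13 over bright members, 4 after median centring and 3 over members that no other list holds. A few changed sign; the cause was not tested. Female-biased genes in the control response went from 0.28 to -0.41 over bright members, at percentile 0.375 and so outside the range as lower. Drug metabolism at 0 h went to 0.0556 as a mean. At 30 h, growth factors went to -0.01 over bright members, and male-biased genes to -0.02 over members that no other list holds and -0.035 after median centring. In the difference of responses, male-biased genes went to 0.13 after cyclic loess and 0.13 after quantile normalization. The number of lists outside their ranges ran from 11 to 21 in the control response, 16 to 21 in the knockdown response, 8 to 11 at 0 h, 8 to 12 at 30 h and 11 to 13 in the difference of responses. These counts hide turnover: against random lists not matched on expression, 11 of 14, 19 of 20, 8 of 11, 5 of 10 and 8 of 13 lists kept their place. There, 1 list was higher and 10 lower at 30 h (6 and 4 when matched), and 0 and 12 in the difference of responses (5 and 8), so the higher calls of the acute phase and ER chaperones in the difference of responses rest on the matching.

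Mcu stayed lower in the knockdown under each rescaling, at -1.93 to -1.97 at 0 h and -1.67 to -1.80 at 30 h. DNA replication and mitosis kept their place outside the random range at 30 h in 8 of 8 alternatives, and G1 to S regulators in 5 of 8. The signal over background is unknown for each array, and it limits what can be said of dim genes.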

Other observations

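The tests weighed here were all chosen after the result was seen. The lower cell cycle genes in knockdown liver at 30 h were set against 3 explanations. A brightness-dependent trend between the arrays was argued against by the median over all 102 genes, -0.85 after cyclic loess (which removes such trends) and -0.80 as deposited (random range after loess -0.13 to 0.08). Tissue taken 1 h after surgery, as the description of that array says, would come before replication genes are induced, yet the 102 genes were higher than at 0 h in the knockdown by a median of 0.55 (random range -0.10 to 0.12). Immediate early genes, which are induced first, go the other way: they stood apart on that array against knockdown 0 h (0.50) and control 30 h (0.22, percentile 99.8), and not in the control response (0.28, percentile 90.2). A difference between pools unrelated to Mcu cannot be told apart from the knockdown, because there is 1 pool per group. An effect of Mcu loss therefore stays open and untested. Further pools per group would be needed to show whether the difference recurs. They would not separate Mcu loss from Cre itself, because only the knockdown mice received Cre.

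Kupffer cell and sinusoidal endothelial markers were lower in the knockdown response than in the control response, with a median of -0.73 over 27 genes. After cyclic loess it was -0.49, below the random range of -0.30 to 0.23, which argues against a brightness-dependent trend as the whole cause. A larger share of resident non-hepatocyte cells in the knockdown tissue at 0 h would raise stellate cell markers too. Their median there was 0.29 as deposited and 0.24 after cyclic loess, at percentile 96.5 of random lists (range -0.23 to 0.26). Cholangiocyte markers had a median of 0.07 there as deposited, inside their range of -0.30 to 0.29. A larger share of such cells therefore cannot be told apart from a change in the cells themselves. All these medians share the 0 h arrays, and 1 unusual pool at 0 h could give them together.

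Clock genes of both phases differed between 0 h and 30 h, in genes chosen after their values were seen. Arntl (-2.02 in control, -1.71 in knockdown) and Nfil3 (-0.99, -0.79) were lower, while Dbp (2.17, 1.45) and Per1 (1.56, 0.97) were higher. The hour of day of each collection is not given in the sources used here. Cdkn1a read 4.05 in control and 5.89 in knockdown liver at 0 h, and 6.67 and 6.59 at 30 h, so its smaller response in the knockdown came with a higher level at 0 h.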
